A study of Mus musculus with 4 samples.

How the data were processed

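RNA was measured in 4 libraries of mouse lymphatic endothelial cells, 1 for each combination of genotype (wild type or homozygous deletion mutant) and culture state. Per the labels' protocols, cells that bore the lymphatic marker LYVE1 and the endothelial cadherin VECAD, and lacked the leukocyte marker CD45, were sorted by flow cytometry from the dorsal anterior part of embryos at day 14.5. All embryos of a litter were pooled for each genotype. A part of each sort went directly into lysis reagent, and the remainder was grown for 7 days on OP9 cells, a mouse stromal line used to support blood cell formation. The medium held FLT3L, IL3 and SCF, each at 100 ng/ml, and cells bearing LYVE1 and VECAD were then sorted again, with no exclusion of CD45 stated for this later sort. Total RNA was made into stranded libraries with a low-input template-switching kit and read in pairs of 75 nt, per the labels' protocols.

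The deposited values are counts of read pairs for each of 23337 gene symbols, with 1 column per library and no normalization. Per the submitters' processing notes, the tools were bcl2fastq, STAR and HTSeq 0.11.2, and the genome build was mm10. The names of the deposited count tables state that duplicates had been removed with sambamba. The annotation, the strand setting and the versions of the other tools are not given in the sources used here. HTSeq appended 5 summary classes to each table, which were kept out of all totals. Read pairs in no annotated gene made up 66.5% of all pairs in the wild type library before culture, 53.6% in the mutant library before culture, 19.996% in the wild type library after culture and 30.3% in the mutant library after culture. In the same order, 21.4%, 34.1%, 67.6% and 56.2% of all pairs did not align, and 7.94%, 8.79%, 9.94% and 10.5% were gene counts. Among uniquely aligned pairs, 89.3%, 85.8%, 66.7% and 74.2% lay in no annotated gene. Pairs that could belong to more than 1 gene came to 0.536% to 0.690% of the gene counts. The Hba and Hbb adult globin genes, which exist as near-identical copies, had no counts, as can happen when multiply aligned reads are left out, and Ccl21a also has near-identical copies, so neither family was interpreted.

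Gene coordinates were taken from GENCODE vM21 on GRCm38, which is the same assembly as mm10. An exon length was found for 22868 symbols, 98.0% of the total. Older symbols were matched to current ones through RefSeq synonyms on the same assembly and kept as deposited, so that Sfpi1 stands for Spi1, Epb4.2 for Epb42 and Pkm2 for Pkm.

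The counts were scaled with the trimmed mean of M values (TMM) of edgeR 4.0.16 in R 4.3.3, with factors of 1.25, 1.16, 0.811 and 0.851 for the wild type and mutant libraries before culture and the wild type and mutant libraries after culture. Levels are TMM-scaled CPM with exact Poisson 95% intervals. A fold is the ratio of 2 such levels, with the 95% Clopper-Pearson interval of the share that 1 library holds of the counts of both. With 1 library per group no comparison has a replicate check, no p-value was computed, and every comparison is between libraries. An additive fit of genotype and culture over the 4 libraries, which would leave 1 residual degree of freedom, was not run. A gene was called higher or lower where its whole interval lay beyond 2-fold, among genes with at least 20 counts in at least 1 of the 2 libraries. A gene with no counts in 1 library was given a bound on its fold, computed with 3 counts in that library. Intervals cover counting error only, since amplified read pairs without molecular identifiers are not independent molecules.

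A total of 33 gene lists, with 468 of 471 distinct members found, was fixed before the data were examined. Each list was described by the median log2 fold of its measured members, computed with a prior count of 2. That median was placed as a percentile among 10000 random lists of equal size, matched on mean expression in 20 bins with seed 1. No percentile was given for lists with fewer than 5 measured members. The genes named in each comparison followed a rule fixed at the same time. It took the 10 genes with the highest lower bound and the 10 with the lowest upper bound of the fold interval, leaving out predicted, mitochondrial, ribosomal protein and small RNA symbols. From each list it took up to 4 called members with the most counts, or 2 where none was called. Prox1, Lyve1, Cdh5, Ptprc, Gata2, Runx1, Flt4, Pdpn, Kit, Sfpi1 and Gata1 were always included. Folds of 3 genes that this rule selects are not reported here, although their lists still count them.

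The procedure was tested on simulated counts with known folds. With counting error alone, 86.0% of genes with a true 4-fold difference were called in the comparison before culture (19074 genes tested), 84.0% after culture (12103 genes), 70.0% for culture of wild type cells (16523 genes) and 85.0% for culture of mutant cells (18407 genes). There was at most 1 false call in each. Adding 30% variation between libraries gave 625 false calls among 18748 unchanged genes before culture and 352 among 11830 after culture, so the number of calls depends on variation that single libraries cannot measure. That setting exceeds the spread of genotype folds beyond counting error among genes with at least 500 counts, 9.93% before and 11.8% after culture. Of 200 simulated lists of 20 genes with no shift, 5.5% fell outside the central 95% of random lists.

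Alternatives fixed in advance were the size factors of DESeq2 1.42.0, total-count CPM, upper-quartile factors, scaling to the summed pan-endothelial genes, thinning to the smallest total, leaving out the 20 most abundant genes from totals, other count minima, other prior counts and other fold thresholds. After the data had been examined, 2 more were added. In the first, a background was subtracted from each gene, equal to the counts per kb of olfactory and vomeronasal receptor genes multiplied by exon length. TMM factors were then computed anew on the remaining counts. This rescaling alone moved all log2 folds by -0.16 before culture and 0.085 after culture between genotypes. It moved them by -0.45 in wild type culture and -0.20 in mutant culture. In the second, genes with 0 counts were set to 3 counts before calling. Calculations outside R used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.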

Results

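The libraries profile lymphatic endothelial cells from mouse embryos at day 14.5, either wild type or homozygous for a deletion, directly after sorting and after 7 days on OP9 stromal cells with blood cytokines. The title of the series names an enhancer bound by the transcription factor GATA2, and its design text gives blood-forming potential as the reason for the culture. The labels do not name the gene that the enhancer controls; in the published study it is Prox1, which encodes the homeobox factor that specifies lymphatic endothelium. Each of the 4 groups holds 1 library, so no value has a replicate and all intervals below are 95% intervals for counting error.

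Gene counts totalled 3987150 in the wild type library before culture, 7943587 in the mutant library before culture, 1694669 in the wild type library after culture and 3931557 in the mutant library after culture. A count was present for 22517, 22608, 19343 and 21536 genes, in the same order. The libraries carried counts in genes that are normally silent outside sensory neurons. Olfactory and vomeronasal receptor genes, 1431 in all, held 6.64 and 8.34 counts per kb of coding sequence in the wild type and mutant libraries before culture, and 0.537 and 1.61 after culture. Extended over all exons, these rates amount to 11.4% and 7.21% of the gene counts before culture, and 2.18% and 2.82% after culture. Genes with few counts before culture were therefore read against this background, and folds with background subtracted are given beside those that move by over 1.5 times. Of the named folds, 149 left their interval with background subtracted and 220 did not, which includes the effect of the rescaling in that setting.

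**Figure D1:**
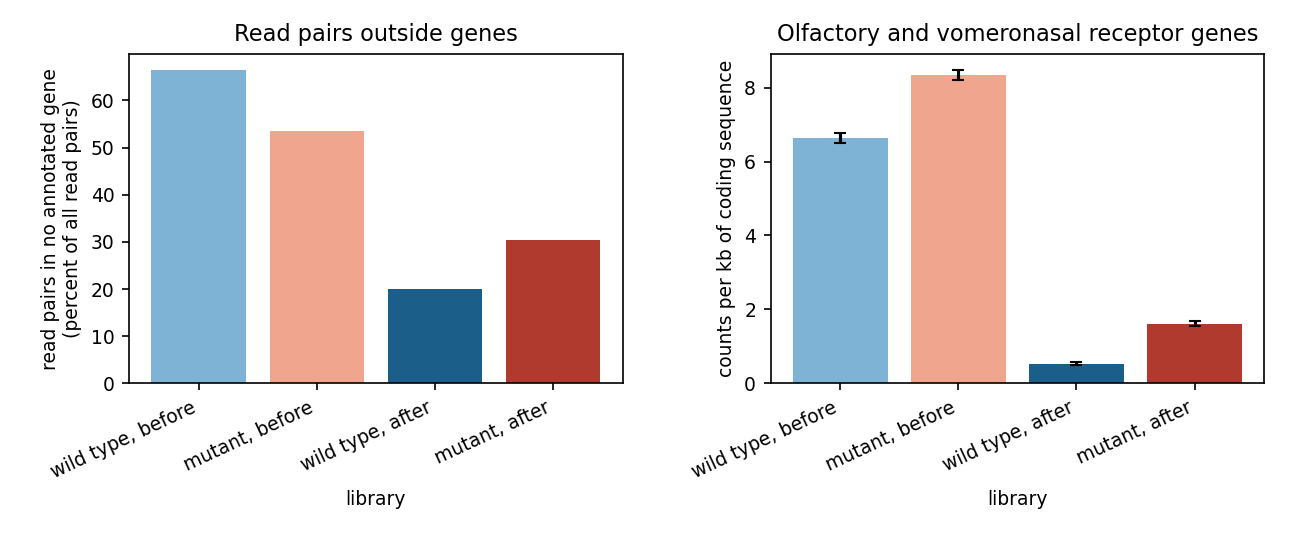
Left, read pairs in no annotated gene as a percent of all read pairs, including pairs that did not align, in each of the 4 libraries. Right, counts per kb of coding sequence over 1431 olfactory and vomeronasal receptor genes, with bars for exact Poisson 95% intervals; the libraries before culture stand at 6.64 and 8.34 counts per kb and those after culture at 0.537 and 1.61.

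Prox1 lies on the minus strand of chromosome 1, from 190118035 to 190170714 in mm10. Its level was 507 CPM (487 to 527) in the wild type library and 487 CPM (472 to 501) in the mutant library before culture, a mutant to wild type fold of 0.96 (0.914 to 1.01). After culture it was 207 CPM (183 to 232) in the wild type library and 137 CPM (125 to 150) in the mutant library, a fold of 0.664 (0.572 to 0.773). Prox1 was thus 2.45-fold lower after culture than before in wild type cells (2.17 to 2.78) and 3.55-fold lower in mutant cells (3.22 to 3.91). The genotype fold after culture was 0.692 times the fold before culture (0.592 to 0.809). With background subtracted, the fold before culture was 0.864 and its interval no longer held 1 (0.822 to 0.908). The rescaling in that setting alone moved all log2 folds by -0.16, so the change reflects the scale rather than counts taken from Prox1. The labels do not say where the deletion lies, so the counts of Prox1 do not check the genotype labels.

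**Figure D2:**
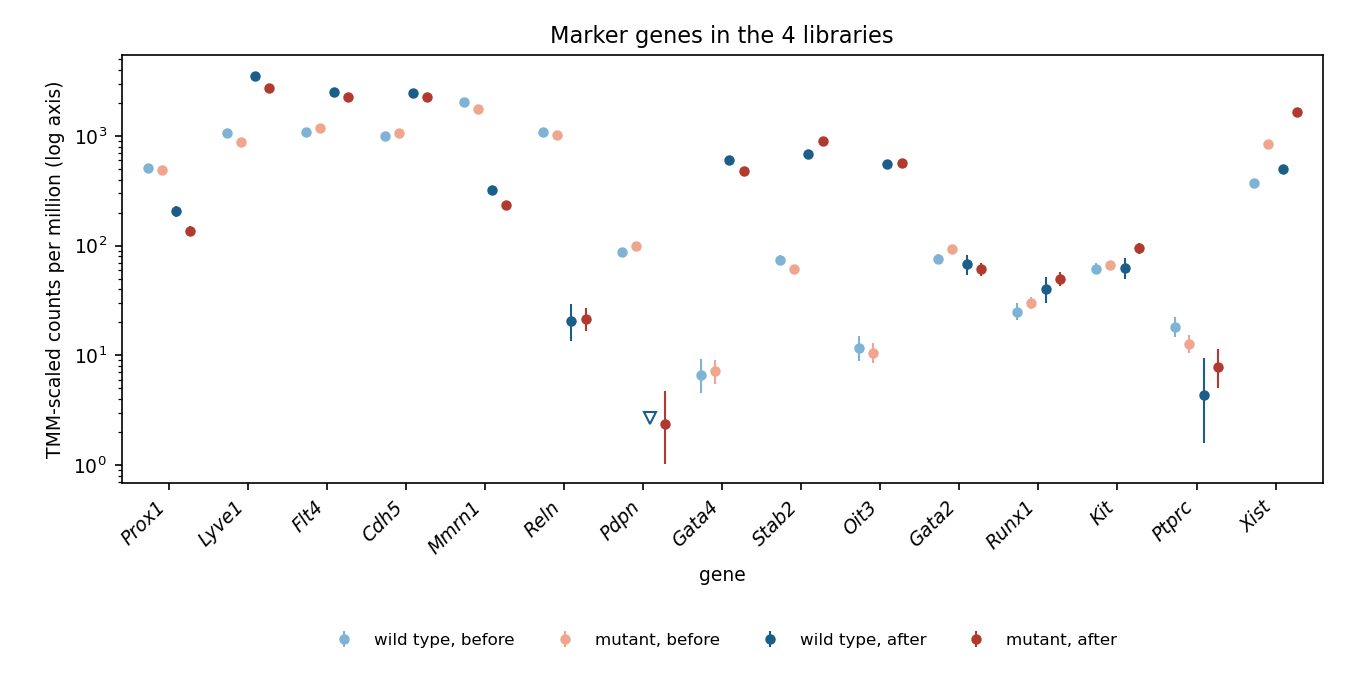
TMM-scaled CPM (log axis) of 15 genes in the 4 libraries, with vertical lines for exact Poisson 95% intervals; the open triangle marks the upper limit for Pdpn in the wild type library after culture, where it had 0 counts. Prox1, Mmrn1, Reln and Pdpn were lower in both libraries after culture, whereas Lyve1, Gata4, Stab2 and Oit3 were higher. These directions held under every scaling tried, but scaled to pan-endothelial counts Lyve1 was only slightly higher.

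The comparison of mutant with wild type cells before culture asks how the deletion alters lymphatic endothelium in the embryo. Genes of the lymphatic identity list were slightly lower in the mutant library relative to matched genes, whereas lymphatic valve genes were not. Lyve1, the hyaluronan receptor used in the sort, had a fold of 0.83 (0.802 to 0.859), Mmrn1, an extracellular protein of lymphatic vessels, 0.867 (0.846 to 0.889), Nrp2, a VEGFC co-receptor, 1.01 (0.988 to 1.04), Flt4, the VEGFC receptor, 1.09 (1.06 to 1.13), and Pdpn, the lymphatic glycoprotein podoplanin, 1.14 (1.01 to 1.28). None of the 25 measured members of the lymphatic identity list was called. Their median log2 fold was 0.02, at percentile 0.895 of random lists, whose median was 0.12, and their summed counts were 0.967 times the wild type level (0.957 to 0.977). With background subtracted the list median was -0.12 and the summed counts were 0.868 times the wild type level (0.859 to 0.877). Nrp2 and Flt4 then stood at 0.91 and 0.98. The rescaling in that setting alone moved all log2 folds by -0.16, which is about the size of these changes. The 15 lymphatic valve genes had a median of 0.17 (percentile 75.4), with 13 above 0 and 2 below. Their summed counts were 1.09 times the wild type level (1.08 to 1.11), or 0.988 times with background subtracted. The 22 pan-endothelial genes had a median of 0.19 (percentile 88.9), with Cdh5, the gene of the sorted cadherin VECAD, at 1.06 (1.03 to 1.10), or 0.952 with background subtracted.

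Stromal and cartilage genes were higher in the mutant library before culture. The stromal list of 21 genes had a median of 0.48 and the cartilage list of 8 genes a median of 0.49, both at percentile 100. The fibrillar collagen genes Col1a1 and Col3a1 had folds of 1.73 (1.67 to 1.79) and 1.51 (1.46 to 1.55), and the cartilage collagen genes Col2a1 and Col11a1 had folds of 1.61 (1.53 to 1.69) and 1.52 (1.41 to 1.64), with no member of either list called. Immediate early genes, which respond to cell dissociation, had a median of 0.34 (percentile 100), with Jun at 1.17 (1.13 to 1.22) and Klf4 at 1.12 (1.08 to 1.16). Glycolysis and hypoxia genes had a median of 0.27 (percentile 99.5), with Gapdh at 1.39 (1.28 to 1.51). The skeletal muscle list had a median of 0.39 (percentile 99.9), and its member Actc1, cardiac actin, was called higher at 2.76 (2.14 to 3.6).

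Blood genes showed no called member between the libraries before culture. The 21 haematopoietic transcription factors had a median of 0.12 (percentile 83.8). The erythroid, lymphoid and neutrophil lists had medians of -0.32, -0.35 and -0.33 (percentiles 4.68, 3.19 and 5.28), with the erythroid list at percentile 1.5 with background subtracted. Summed erythroid and neutrophil counts were 0.802 (0.726 to 0.887) and 0.837 (0.745 to 0.941) times the wild type level, while summed mast cell counts were 1.18 times (1.07 to 1.31). Gata2 had a fold of 1.23 (1.09 to 1.39), Lmo2 1.10 (1.0 to 1.21) and Runx1, the factor required for emergence of blood cells from endothelium, 1.19 (0.963 to 1.49). Kit, the SCF receptor, stood at 1.07 (0.932 to 1.23). Ptprc, which encodes CD45, had 118 counts in the mutant and 91 in the wild type library, a fold of 0.701 (0.529 to 0.932). The myeloid factor Sfpi1, with 31 and 26 counts, and the erythroid factor Gata1, with 38 and 25 counts, lay close to the background.

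Of 18934 genes measured before culture, 3 were called higher and 9 lower in the mutant library. The genes called higher were Mdfic, a regulator of transcription, at 2.85 (2.49 to 3.27), Actc1, and Xist, the RNA of the inactive X chromosome, at 2.27 (2.16 to 2.39). Next by lower bound were Hist1h4k at 2.54 (1.99 to 3.27), Tmsb10 at 2.23 (1.95 to 2.57) and the WNT antagonist Sfrp2 at 2.22 (1.92 to 2.58). Col10a1, a collagen of hypertrophic cartilage, was called lower, with 36 counts against 226 and a fold of 0.0862 (0.0588 to 0.123), or 0.0233 with background subtracted. Ptpn20, Pln, Slc22a28, Nipal2 and Tpbpa were also called lower, at folds of 0.22 to 0.29 on 9 to 63 counts. With background subtracted Ptpn20 stood at 0.0656 and was still called, while Pln, Slc22a28, Nipal2 and Tpbpa, at 0.0937, 0.0776, 0.118 and 0.129, had intervals that reached past 1 and were not. With background subtracted 4 genes were higher and 6 lower, and 3 of the 9 lower genes were shared. The litter sex list, which holds Xist and Y-linked genes, had a median of -0.81 (percentile 0), with Xist higher and the 4 Y-linked genes lower in the mutant library. These genes depend on the sex of the pooled embryos, so their folds before and after culture are not read as effects of the deletion.

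**Figure D3:**
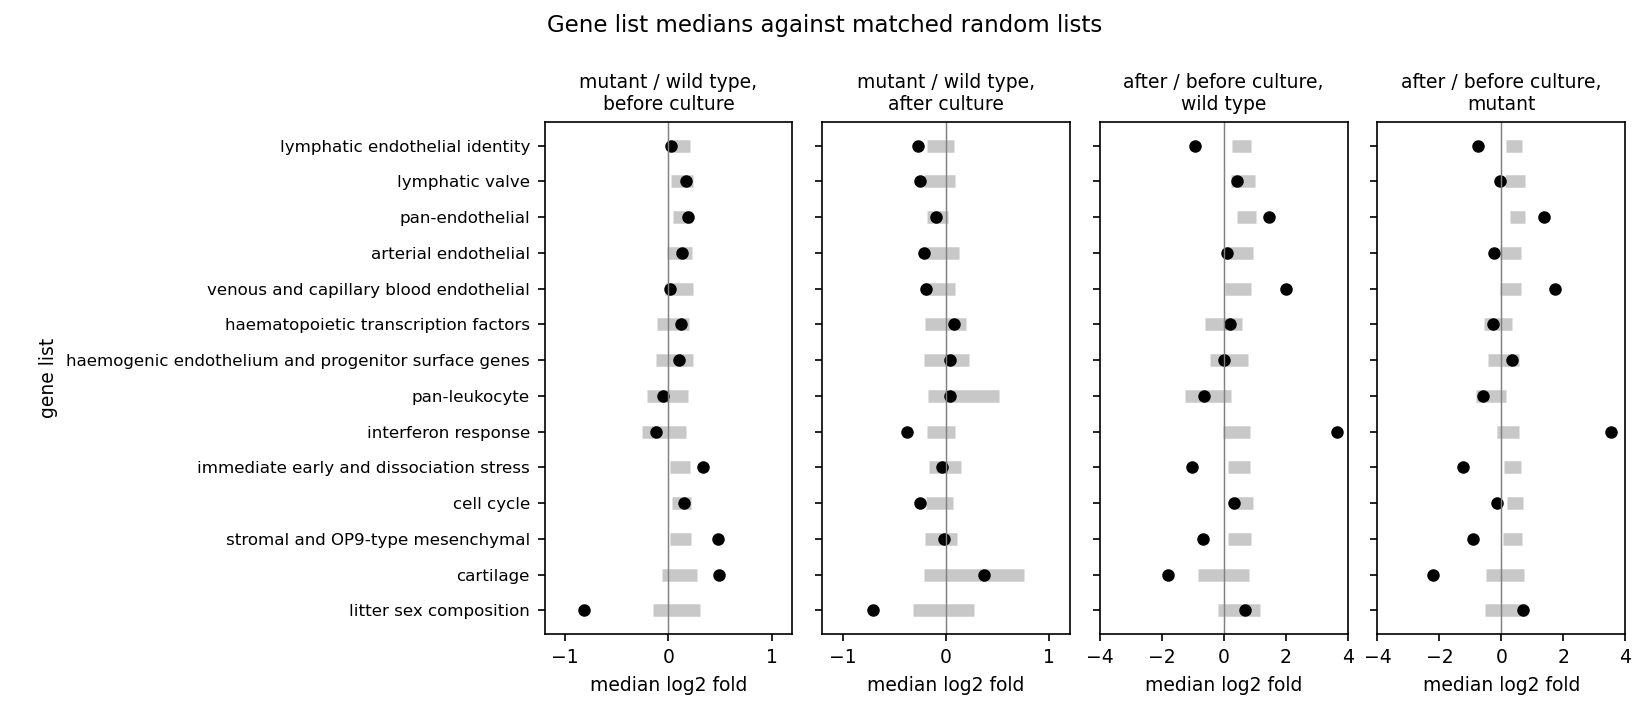
Median log2 fold of 14 gene lists (points) in the 4 comparisons, against the central 95% of 10000 matched random lists (grey bars); the horizontal range is wider in the culture panels. The interferon list stood at 3.67 and 3.55 after culture, and the lymphatic identity list at -0.92 and -0.77.

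After culture, the same comparison of genotypes covers only cells that again bore LYVE1 and VECAD. Blood cells without these markers would be removed by that sort, so the libraries do not measure how many blood cells either genotype formed. Lymphatic genes were slightly lower in the mutant library. The 21 measured lymphatic identity genes had a median log2 fold of -0.27 (percentile 0.0300) and the 14 lymphatic valve genes a median of -0.25 (percentile 0.640), with no member called. Lyve1 had a fold of 0.778 (0.751 to 0.806), Flt4 0.894 (0.859 to 0.931) and Stab1, a scavenger receptor, 0.968 (0.929 to 1.01). The pan-endothelial median was -0.10 (percentile 37.9), with Cdh5 at 0.922 (0.886 to 0.961) and Eng, a TGF-beta co-receptor, at 0.837 (0.808 to 0.867). Arterial genes had a median of -0.21 (percentile 2.99) and venous and capillary genes -0.19 (percentile 6.58). Summed counts were 0.866 times the wild type level for lymphatic identity, 0.876 for valve, 0.912 for pan-endothelial, 0.923 for arterial and 0.844 for venous and capillary genes. Lower sums were thus not particular to lymphatic genes.

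When the cultured libraries were compared, the blood lists with at least 5 measured genes lay inside the range of random lists, except the mast cell list, which lay below it. Blood lists with fewer measured genes were not placed among random lists. The 14 measured haematopoietic transcription factors had a median of 0.08 (percentile 81.5), the 10 progenitor surface genes 0.04 (percentile 66.4) and the 10 pan-leukocyte genes 0.04 (percentile 27.0), with no member of these lists called. Other lists differed in sign. The 8 cytokine receptor genes were all above 0, with a median of 0.27 (percentile 79.3) but summed counts at 1.05 times the wild type level (0.994 to 1.12), and the 6 macrophage genes had a median of 0.54 (percentile 96.4), with summed counts of the list at 1.35 times the wild type level (1.22 to 1.51). Summed erythroid and lymphoid counts stood at 1.98 (1.53 to 2.61) and 1.32 times (1.03 to 1.71), with only 3 and 4 genes measured, whereas the 4 megakaryocyte genes were all below 0, with a sum of 0.936 (0.854 to 1.03). Kit stood at 1.52 (1.19 to 1.95), Runx1 at 1.25 (0.915 to 1.73), Gata2 at 0.902 (0.702 to 1.17) and Itga2b, an integrin of early progenitors, at 0.994 (0.854 to 1.16). The leukocyte adaptor gene Hcls1 had a fold of 1.98 (1.40 to 2.84). Ptprc had 26 counts in the mutant library and 6 in the wild type library, a fold of 1.78 (0.717 to 5.29), so a difference was not detectable at this depth. Sfpi1 and Gata1 had 3 and 4 counts in the mutant library against 5 and 2 in the wild type library.

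Of 12309 genes measured after culture, 30 were called higher and 9 lower in the mutant library. Of those 30, 22 had 0 counts in the wild type library, the shallowest of the 4. Il1f5, Adamts8, Gatsl3, Ccdc27, Cdh17 and Mpv17l were among these, with 33, 31, 25, 24, 24 and 24 counts in the mutant library, at least 4.52-fold higher for Il1f5 and at least 3.29-fold higher for Mpv17l with 3 counts in place of 0, where the 95% intervals begin at 3.48 and 2.47. Counting 3 for each 0 left 8 genes higher, and 3 of the 30 were also called with background subtracted. Xist was called higher at 3.33 (3.08 to 3.61), with the Y-linked genes Kdm5d at 0.352 (0.254 to 0.489) and Uty at 0.398 (0.296 to 0.535).

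Among genes lower in the cultured mutant library were 3 mast cell protease genes. The list of mast cells, basophils and eosinophils had a median of -2.98 (percentile 0) over 5 measured genes, with summed counts at 0.261 times the wild type level (0.209 to 0.325). Cpa3, mast cell carboxypeptidase, had 5 counts against 68, a fold of 0.0302 (0.00951 to 0.074), or 0.0195 with background subtracted; Cma1, a chymase, had 7 against 40, a fold of 0.0719 (0.0272 to 0.162); and Mcpt4 had 8 against 30, a fold of 0.11 (0.0434 to 0.245). Some genes that fat cells express were also called lower, namely Car3 at 0.0754 (0.0357 to 0.145), the adipokine gene Adipoq at 0.236 (0.158 to 0.347) and Aoc3 at 0.235 (0.142 to 0.381). The interferon list of 18 genes had a median of -0.38 (percentile 0), with Ddx58 at 0.854 (0.760 to 0.962). The cell cycle list had a median of -0.25 (percentile 0.22), with Top2a at 0.791 (0.723 to 0.866) but Mki67 at 1.08 (1.01 to 1.15).

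Comparing wild type cells after culture with those before it shows what the culture altered without the deletion. Several genes that mark lymphatic endothelium were far lower after culture. Reln, a secreted protein of lymphatic endothelium, was 53.5-fold lower (37.0 to 80.6), or 92.9-fold with background subtracted, Mmrn1 6.34-fold lower (5.76 to 6.99), and Pdpn, with 435 counts before and 0 after, at least 40.0-fold lower with 3 counts in place of 0, where the 95% interval begins at 32.4. Of the 25 lymphatic identity genes, 10 were called lower and 6 higher, with a median log2 fold of -0.92 (percentile 0). Lyve1 and Flt4, in contrast, were 3.29-fold (3.16 to 3.42) and 2.33-fold (2.23 to 2.43) higher, and the summed counts of the list were 1.10 times the level before culture (1.08 to 1.12), opposite in sign to the median, but 0.814 times (0.800 to 0.828) with background subtracted. The rescaling in that setting alone moved all log2 folds by -0.45, so the direction of the sum depends on the scaling.

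Pan-endothelial, venous and capillary genes were higher after culture of wild type cells, as were some genes of sinusoids. Of 22 pan-endothelial genes 14 were called higher and none lower, with a median of 1.45 (percentile 100), and Eng stood at 14.3 (13.4 to 15.3). Of 16 venous and capillary genes 10 were called higher and 2 lower, with a median of 2.0 (percentile 100); the fatty acid receptor gene Cd36 had a fold of 16.8 (15.0 to 18.9) and Plvap, which forms the diaphragms of fenestrae, 8.16 (7.46 to 8.94). Gata4, a transcription factor of heart and liver sinusoid endothelium, rested on 33 counts before culture and 826 after, a fold of 90.7 (64.1 to 133), or 210 with background subtracted. Oit3, a gene of liver sinusoids, had a fold of 47.3 (36.1 to 62.8), the scavenger receptor gene Stab2 9.26 (8.19 to 10.5) and the clotting factor gene F8 34.8 (29.7 to 40.9). The liver and sinusoid list, which also holds genes of hepatocytes, had a median of -1.11 (percentile 37.3), with 3 of 9 genes called higher. Its summed counts were 8.05 times the level before culture (7.39 to 8.76), opposite in sign to the median. Of 18 interferon response genes 17 were called higher, with a median of 3.67 (percentile 100) and Ifi44 at 37.4 (27.5 to 52.0).

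Blood genes moved in both directions in the wild type culture. Csf2rb2 and Csf2rb, which encode beta chains of the IL3 receptor, had folds of 55.1 (43.1 to 71.5) and 16.3 (12.8 to 21.1), Itga2b 12 (9.21 to 15.8) and Clec1b, the podoplanin receptor, 29.7 (19.0 to 48.5). Of the 19 haematopoietic transcription factors, 3 were called higher and 1 lower, with a median of 0.19 (percentile 66.4). With background subtracted the median was 0.38 (percentile 96.8) and no member was called lower. Hhex, at 3.29 (2.78 to 3.90), and Zfpm1, at 5.11 (4.14 to 6.32), were higher; Runx1 stood at 1.60 (1.14 to 2.21) and Gata2 at 0.890 (0.701 to 1.12). Ptprc had 6 counts after culture and 91 before, a fold of 0.239 (0.0855 to 0.541), or 0.151 with background subtracted.

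Immediate early, stromal and cartilage lists had medians below 0 after culture of wild type cells. Of 23 immediate early genes 6 were called lower and none higher, with a median of -1.01 (percentile 0), and Klf4 was 8.29-fold lower (6.95 to 9.97). Of 21 stromal genes 7 were called lower and 5 higher, with a median of -0.65 (percentile 0), Col3a1 6.33-fold lower (5.60 to 7.17) and Bgn, in contrast, higher at 5.16 (4.45 to 5.99). Of 8 cartilage genes 5 were lower, with a median of -1.80 (percentile 0). In all, 1401 of 17154 genes were called higher and 989 lower. Scaling by total counts moved all log2 folds by -0.62 and gave 516 higher and 2983 lower, subtracting background gave 892 and 610, and scaling to pan-endothelial counts moved all log2 folds by -1.67. Under that last scaling Cdh5 stood at 0.777 and Flt4 at 0.733, so the higher levels of these genes hold relative to most genes and not relative to other endothelial genes. Genes of similar expression were also higher. Random lists matched to the pan-endothelial and lymphatic identity lists had median log2 folds of 0.72 and 0.56, so part of these higher levels was shared with such genes.

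The same comparison in mutant cells gave a similar picture. Reln was 47.0-fold lower (37.3 to 60.1), or 72.5-fold with background subtracted, Mmrn1 7.44-fold lower (6.92 to 7.995) and Pdpn had 8 counts after culture against 915 before. Of the 25 lymphatic identity genes, 10 were called lower and 4 higher, with a median log2 fold of -0.77 (percentile 0); Klhl4 stood at 0.383 (0.357 to 0.411) and Lyve1 at 3.08 (2.99 to 3.18). The pan-endothelial median was 1.39 (percentile 100), with 13 of 22 genes called higher, and the venous and capillary median was 1.73 (percentile 100). Gata4 had a fold of 67.0 (52.4 to 87.1), or 102 with background subtracted. Oit3 had a fold of 54.2 (44.2 to 67.2), Stab2 14.9 (13.6 to 16.3), F8 52.4 (45.9 to 60.0) and the endothelial receptor gene Gpr182 25.6 (21.6 to 30.6). The liver and sinusoid list had a median of -0.91 (percentile 4.76), but its summed counts were 9.93 times the level before culture (9.36 to 10.5).

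Interferon genes were also higher in the mutant culture, with 16 of 18 called, a median of 3.55 (percentile 100) and Ifi204 at 69.9 (46.9 to 109), or 258 with background subtracted. Csf2rb2 had a fold of 53.4 (44.8 to 64.2), Itga2b 12.2 (10.1 to 14.9), Clec1b 30.3 (21.3 to 44.4), Runx1 1.67 (1.37 to 2.03), Kit 1.44 (1.25 to 1.65) and Gata2 0.651 (0.556 to 0.759). The 21 haematopoietic transcription factors had a median of -0.28 (percentile 17.3), or 0.09 (percentile 78.5) with background subtracted, with 3 called higher and 2 lower, among the latter Lmo2 at 0.418 (0.359 to 0.484). The mast cell gene Cpa3 had 5 counts after culture against 239 before, a fold of 0.0576 (0.0185 to 0.136), or 0.0316 with background subtracted. Of 23 immediate early genes 12 were called lower, with a median of -1.24 (percentile 0), and the stromal and cartilage medians were -0.92 and -2.21, both at percentile 0.

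In the mutant culture, 976 of 18807 genes were called higher and 680 lower. Scaling by total counts moved all log2 folds by -0.45 and gave 493 higher and 1850 lower. Scaling to pan-endothelial counts moved them by -1.43 and put Cdh5 at 0.798. Random lists matched to the pan-endothelial and lymphatic identity lists had median log2 folds of 0.52 and 0.40. Among 17012 genes measured in both genotypes, 838 of the 1401 genes higher in wild type culture were also among the 965 higher in mutant culture, where independent lists would share 79.5. For lower genes, 289 of 986 were among the 640 lower in mutant culture, where 37.1 would be shared. These expected numbers take every gene as equally likely to be called, whereas a call needs enough counts. Some excess over them would arise from that alone. Across genes, which are not independent replicates, log2 folds of culture in the 2 genotypes had a Pearson r of 0.786 and a Spearman rho of 0.832. Log2 folds of genotype before and after culture had an r of -0.15 and a rho of -0.13 over 12294 genes.

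Genes with at least 500 counts in both libraries show how widely folds were spread within each pair beyond counting error. The spread of their folds beyond that error was 9.93% between genotypes before culture (1691 genes) and 11.8% after culture (515 genes). It was 46.8% between culture states in wild type cells (466 genes) and 33.6% in mutant cells (1779 genes). No replicate shows how much of these spreads would recur between sorts of 1 genotype.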

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

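Tests of a background spread over the genome and of amplification noise were chosen only after the results they bear on had been seen; the tests of strand and of adipocyte genes were written before their values were computed, but a condition on the stromal list was added to the latter afterwards.

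Many read pairs lay outside annotated genes, in data the comparisons do not use: 66.5% of all pairs in the wild type library and 53.6% in the mutant library before culture, and 19.996% and 30.3% after culture. Among uniquely aligned pairs the shares were 89.3% and 85.8% before culture and 66.7% and 74.2% after culture. Counting on the opposite strand is argued against, because for 16 antisense genes the partner genes held 97.1% and 97.2% of the summed counts before culture and 98.6% and 97.2% after culture, in the same order. Most of these counts belong to Igf2. Without it the partners held 83.9%, 88.1%, 92.5% and 89.8%, which still exceeds the antisense genes but meets the bound set beforehand in 1 library only. Xist, a separate pair, held 42.1 to 120 times the counts of its antisense gene Tsix. A background spread over the genome, such as genomic DNA, may account for some or much of these pairs. The rate in olfactory and vomeronasal receptor genes, extended to both strands of the genome, predicts 108% and 93.7% of them before culture and 85.8% and 77.2% after culture. Extension to both strands assumes that pairs were counted by strand. The strand setting is not given, and without that assumption the predicted shares would be far lower. These shares are also uncertain because other families had different rates. Against 6.64 and 8.34 counts per kb in the receptor genes before culture, trace amine receptor genes had 9.91 and 12.1, and beta-defensin genes, with only 10.3 kb of coding sequence in all, 32.7 and 46.2. Unspliced RNA of expressed genes was not tested and stays open for the remainder. No biological explanation was tested for this pattern.

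Culture folds of Cpa3 went in opposite directions, 3.42 (2.42 to 4.84) in wild type and 0.0576 (0.0185 to 0.136) in mutant cells; the difference between them was not tested, since each rests on 1 library per state. Before culture Cpa3 was higher in the mutant library, at 1.80 (1.37 to 2.37), as were the summed mast cell genes at 1.18 (1.07 to 1.31). Cpa3 was 1 of 3 genes of the mast cell list among the 9 genes lower in the cultured mutant library, where chance gives 0.00366, and none of 10000 draws of matched random genes put as many in any 1 of the fixed lists, which argues against isolated amplified fragments of single genes as the cause. A separate list of adipocyte genes had its median of -0.64 at percentile 0.025 in the same comparison, over only 5 measured genes with none called. Its members Pnpla2 and Acsl1 stood at 98.1 and 41.3 CPM in the mutant and 153 and 72.0 CPM in the wild type library, but Plin4 at 52.0 and 39.3 CPM. The stromal list, which OP9 cells would also bring, had a median of -0.02 (percentile 66.1) with 9 genes above and 9 below 0, so whether more adipocyte-type OP9 cells were in the wild type sort stays open for the fat cell genes. Sorting for LYVE1 and VECAD would remove cells that lack them, and an effect of the deletion on mast cells stays open and untested, as does chance variation between single cultures.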

How the results depend on the processing

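No paired analysis was possible for any single comparison because each rests on 1 library per group, and no library could be left out of one. A fit of culture over both genotypes, paired by sort, was not run. Background subtraction and setting 0 counts to 3 were chosen after the data were seen; the other settings were fixed before. Of 132 list medians, 130 moved by less than their spread under DESeq2 size factors, 102 under total-count CPM and 112 with background subtracted. Among named gene folds, 362 stayed within their interval and 7 left it under DESeq2 size factors, against 194 and 175 under total-count CPM. The cause was not tested for the results below, except that a rule made stricter or looser changes a count by construction and that a scaling moves all folds of a comparison alike. Leaving the 20 most abundant genes out of totals kept all counts of called genes within 1.5 times. Depth limits the cultured wild type library most, where 22 of the 30 genes called higher in the mutant had 0 counts.

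Counts of called genes moved as follows. Before culture, genes higher in the mutant numbered 132 where the fold had only to exceed 2 with an interval leaving out 1, and 0 where the interval had to pass 4-fold. Lower genes numbered 342 and 1 under those rules, 20 with no filter, 3 with at least 50 counts, 17 with total-count CPM and 15 with upper-quartile factors. After culture, higher genes numbered 460 and 0 under the fold rules, 3 with at least 50 counts, 4 after thinning, 5 with background subtracted and 8 with 0 counts set to 3. Lower genes numbered 82 and 4, then 19 with no filter and 4 with at least 50 counts. In wild type culture, higher genes numbered 2699 and 291 under the fold rules, 516 with total-count CPM, 657 with upper-quartile factors and 892 with background subtracted. Lower genes numbered 4219 and 96, then 2983, 2304 and 610. In mutant culture, higher genes numbered 1696 and 248 under the fold rules, 493 with total-count CPM and 574 with upper-quartile factors. Lower genes numbered 3513 and 132, then 1850 and 1437, and 413 after thinning.

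Several list medians moved or changed sign. The lymphatic identity median before culture changed sign to -0.087 with total-count CPM and to -0.12 with background subtracted. The pan-endothelial median became 0.0508 before culture and -0.0159 after culture with background subtracted, and -0.0299 after culture with total-count CPM. In wild type culture it became 0.83 with total-count CPM and 1.04 with background subtracted. Also in wild type culture, the megakaryocyte list, at 0.19 in the main setting, changed sign to -0.38 with total-count CPM and -1.02 with no filter. The cell cycle list, at 0.33, changed sign to -0.29 with total-count CPM and -0.0590 with background subtracted. In mutant culture the endothelial-to-mesenchymal list changed sign to 0.49 with no filter and the arterial list to 0.23 after thinning.

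The fold of Prox1 before culture became 0.891 with total-count CPM, 0.890 scaled to pan-endothelial counts, 0.864 with background subtracted and 0.896 with upper-quartile factors; after culture it stayed between 0.639 and 0.728. In wild type culture Prox1 became 0.265, 0.128, 0.30 and 0.299 in the same order of settings, and in mutant culture 0.207, 0.105, 0.242 and 0.224. Scaling to pan-endothelial counts put genes that had been called higher after culture below 1. Among reported genes these were, in wild type culture, Cd93 0.979, Cdh5 0.777, Ephb4 0.925, Flt4 0.733, Lcp1 0.984, Notch1 0.875, Pecam1 0.841, Pgk1 0.822, Pkm2 0.954 and Tie1 0.739. In mutant culture these were Cd93 0.902, Cdh5 0.798, Ephb4 0.892, Lcp1 0.991, Pecam1 0.919, Pkm2 0.952 and Smyd2 0.866. Genes higher without a call went below 1 too, such as Runx1, to 0.502 in wild type and 0.62 in mutant culture, and Flt4 and Kit, to 0.709 and 0.534 in mutant culture. The correlation across genes of genotype folds after and before culture became -0.0901 with at least 50 counts and -0.0210 with background subtracted.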

Other observations

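Tests of feeder cells, of background in the lymphatic list and of the endothelial share were chosen only after the result was seen. Those of the sinusoidal and endocardial lists were written before their values were computed, but a further condition on each was added after them.

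Lists of cell types outside the endothelium mostly had medians below 0 after culture, several of them inside the range of random lists. Background made up 29.1%, 36.3% and 56.4% of the counts of the epithelial, skeletal muscle and neural lists in the wild type library before culture. The epithelial list had a median log2 fold of -1.52 in wild type culture (percentile 18.5) and -1.31 in mutant culture (percentile 0.27), where 4 of 10 genes were called lower, among them the keratin genes Krt14 at 0.222 (0.124 to 0.369) and Krt5 at 0.266 (0.142 to 0.461). The neural and Schwann list had medians of -1.06 (percentile 61.6), or -0.57 (percentile 95.2) with background subtracted, and -1.19 (percentile 2.88), with Dcx, a gene of young neurons, at 0.11 (0.0469 to 0.221) in mutant cells, or 0.0584 with background subtracted. Skeletal muscle genes had medians of -1.76 (percentile 4.17) and -1.49 (percentile 0.0600), the latter -2.22 with background subtracted, with the titin gene Ttn at 0.277 (0.230 to 0.33) and 0.421 (0.382 to 0.464). Macrophage genes had medians of -1.30 (percentile 15.4) and -0.84 (percentile 11.3), with Csf1r at 0.210 (0.0826 to 0.445) in wild type cells, or 0.137 with background subtracted, but their summed counts in mutant cells were 1.03 times the level before culture (0.968 to 1.09). Smooth muscle and pericyte genes were mixed, with medians of -0.07 and 0.03 and Acta2 at 7.93 (6.0 to 10.6) and 5.52 (4.63 to 6.61).

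Members of the arterial list went apart in culture. Hey1, a target of Notch, stood at 0.160 (0.109 to 0.228) in wild type and 0.0788 (0.0568 to 0.107) in mutant cells, whereas the receptor gene Nrp1 stood at 8.48 (7.61 to 9.48) and 6.82 (6.36 to 7.32) and the chemokine gene Cxcl12 at 18.7 (15.8 to 22.4) and 13.9 (12.5 to 15.6). The arterial list medians were 0.10 (percentile 2.72), or -0.16 with background subtracted, and -0.24 (percentile 0.35). Among genes near Prox1 on chromosome 1, which had medians of 0.01 before and -0.03 after culture between genotypes, Smyd2 stood at 2.33 (2.10 to 2.58) in mutant culture.

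Lower lymphatic genes with higher levels of some sinusoidal genes after culture were weighed against 3 technical explanations. The liver and sinusoid list had medians of -1.11 and -0.91, but summed counts of 8.05 and 9.93 times the level before culture. For feeder cells or other stroma in the sort, the summed stromal list was 0.611 times its level before culture in wild type cells and 0.359 times in mutant cells. This cannot exclude feeder cells, because the sorts before culture already held stromal genes, at 4518 CPM in wild type and 6653 CPM in mutant cells. The adipocyte list was higher in culture, with medians of 1.45 (percentile 99.97) in wild type and 0.33 (percentile 98.1) in mutant cells. In wild type culture 5 of its genes were above 0 and 1 below, and in mutant culture 5 and 4. Background before culture is argued against, since the lymphatic identity median was -1.36 and -0.91 with background subtracted. The rescaling in that setting alone moved all log2 folds by -0.45 and -0.20, so the subtraction itself had little part in these values. Background made up 1.30% and 0.913% of the list's summed counts in the wild type and mutant libraries before culture. A higher share of otherwise unaltered endothelial cells is argued against by the main setting. There the lymphatic identity median lay below the pan-endothelial median, by a difference of -2.37 in wild type and -2.16 in mutant cells. Outgrowth of a different LYVE1-bearing endothelium and a shift within the cells themselves may each account for the pattern, and neither was tested.

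The nature of the cultured endothelium was examined as a hypothesis with a pair of separate lists. A list of 12 hepatic sinusoidal endothelial genes had a median of 0.77 (percentile 99.0) in wild type and 1.01 (percentile 99.98) in mutant culture, with 3 genes called higher in each. In wild type culture 8 of its genes were above 0 and 4 below, and in mutant culture 11 and 1. That met the condition written beforehand, a median above the central 95% of random lists in both genotypes. A comparison with the pan-endothelial list was added only after these values were seen, and the pan-endothelial medians of 1.45 and 1.39 were higher still. A hepatic sinusoidal type and endothelium in general cannot be told apart by this list, because a higher level of all endothelial genes would raise it too. The members with the most counts over all libraries, Ctsl and Plxnc1, stood at 479 and 88.0 CPM in the wild type library after culture and at 79.5 and 26.9 CPM before. A list of 8 endocardial genes lay at percentiles 26.4 and 49.2. The condition written beforehand counted this against an endocardial type, but 3 genes were above 0 and 5 below in each genotype, the 5 with 2 to 5 counts in the cultured wild type library and 0 to 25 in the cultured mutant library, so an endocardial type stays open.

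Counts of silent receptor genes varied more than counting error allows. Over 1080 olfactory receptor genes of similar coding length, the variance was 5.59 and 9.09 times the mean in the wild type and mutant libraries before culture, and 1.91 and 2.75 times after culture. Differences in how uniquely reads map to each gene are part of this value and were not separated from clumped amplification.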
